A study of Mus musculus with 20 samples.

How the data were processed

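Liver RNA of 20 male mice, 5 each of the strains NZO/Hl (NZO), C57/Bl6, C3H and 129P2/OlaHsd, was hybridized to 1 whole-transcript array per animal. Per the labels' protocols, animals were 6 weeks old, had eaten a high-fat diet (45 kcal% fat, 20 kcal% protein, 35 kcal% carbohydrate, 4.73 kcal/g) since weaning at 21 days, and gave RNA with an integrity number above 8, of which 150 ng was amplified. The deposited log2 values were made with Affymetrix Expression Console by robust multi-array average (RMA), per the submitters' processing notes, which state no versions. These log2 values were used as deposited. The labels carry no replicate numbers, so animals are numbered within a strain in the order of the series.

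Probe sets were named from the platform annotation given with the series. Of 35556 probe sets, 21789 had 1 gene symbol, 1621 had several and 12146 were unnamed here; only those with 1 symbol were used. Of these, 21698 were matched by Entrez identifier to the GRCm38.p6 gene annotation, which changed 0 symbols and was used for names and the order of genes only, as the series states no genome build. For the 999 genes with several probe sets, the probe set with the highest mean over all arrays was taken. A gene was tested where at least 5 arrays held a value above their own 40th percentile over all probe sets, which left 14190 of 19938 genes and set aside 5748. The same percentile served as the floor for levels: where all 5 values of a strain lay under it, a difference from a brighter strain is a bound, that strain's mean minus the mean percentile of the dimmer strain's arrays. For some genes dim on fewer arrays, the difference with dim values raised to that percentile is also given. Both rules were added after the data were seen.

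Differences were tested with limma 3.58.1 in R 4.3.3 (package data.table, version 1.17.8), with 1 mean per strain over all 4 strains (16 residual and 6.37 prior degrees of freedom), empirical Bayes moderation with an intensity trend, and Benjamini-Hochberg adjustment over the tested genes at an adjusted p of 0.05. No covariate was used. The 6 pairwise comparisons and the moderated F-test over all strains come from this fit. A gene set apart in a strain passed all 3 of its comparisons in the same direction. Nudt19 was also tested by exact two-sided permutation. Of 46 gene lists written beforehand, the 45 with at least 5 tested genes went to limma's camera with a preset correlation of 0.01, with the Benjamini-Hochberg adjustment over lists; camera with an estimated correlation and fry were alternatives. For each list, calls were also counted with p-values adjusted over the list alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

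The design, the lists, the settings to be varied and the rule for named genes were fixed before the data were examined. Named genes were Nudt19, the 6 largest differences each way in each NZO comparison among called genes whose values did not overlap between the strains, the 10 each way that set NZO apart and the 4 each way that set each other strain apart, by their smallest difference and also without overlap, the 3 largest each way in the other comparisons, and up to 3 leading members of each list past the camera test. Called members of the lists on Nudix hydrolases and coenzyme A and measured members of the list on reported strain differences could be named as well; of the first 2 lists those called in NZO comparisons are. Symbols of predicted genes, clones, small RNAs, olfactory receptors and gene segments were counted but not named in the ranked parts. The neighbours of Nudt19 were named for their place.

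Results were recomputed with no filter or a stricter filter on dim genes (60th percentile), equal array medians, another quantile normalization, no intensity trend, robust moderation, array weights, only the compared strains in the fit, the mean of a gene's probe sets, a test against a fold of 1.2, a fold of at least 2, and without each animal in turn. Array spread as a covariate and leaving out the 3 arrays of narrowest spread were added after the data were seen. The depth of a count table has no counterpart on arrays, whose number limits the precision.

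The fit was tested on simulated data with 14190 genes, of which 200 were changed. For NZO minus B6, 83.6% of genes changed by 0.5 log2 units, 95.5% of those changed by 1 and 98.5% of those changed by 2 were called, with 10 false calls among 195. For NZO minus C3H the shares were 86.6%, 95.5% and 98.5%, with 12 false calls among 199, and for NZO minus 129P2 83.6%, 98.5% and 100%, with 7 among 195. Of 200 genes simulated as set apart in NZO, 178 were called, with 2 false calls. A simulated list shifted by 0.3 was called by camera, and 0 of 44 other lists were. The simulated genes varied independently of each other, and array spread was not simulated. So this tests neither false calls of lists whose genes move together nor false calls of single genes that follow array spread.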

Results

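Liver transcript levels were measured on whole-transcript microarrays in 20 male mice of 4 inbred strains, with 5 animals a strain. The strains were NZO/Hl (NZO here), a model of obesity and diabetes, C57/Bl6 (B6 here), C3H and 129P2/OlaHsd (129P2 here). The animals were 6 weeks old and had eaten a high-fat diet, with 45% of its calories from fat, since weaning at 21 days. The arrays were made to find candidate genes, and the series as a whole concerns the knockdown of Nudt19, a peroxisomal Nudix hydrolase that cleaves coenzyme A. None of these arrays is of a knockdown. Expression values are on the log2 scale, so a difference of 1 is a 2-fold difference. The number of arrays limits the precision: the differences printed below have standard errors (SE) from the limma fit over all 4 strains, and group means have standard deviations (SD, n = 5). A value under the 40th percentile of its own array over all probe sets is called dim here. Where a gene was dim on all 5 arrays of a strain, its difference from a brighter strain is given as a bound, the brighter strain's mean minus that percentile.

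Arrays of the same strain were more alike than arrays of different strains, with median pairwise correlations over all probe sets of 0.985 and 0.979. Arrays also differed in the spread of their values. The interquartile range of an array was 2.43 ± 0.057 in B6, 2.33 ± 0.111 in NZO, 2.31 ± 0.088 in C3H and 2.32 ± 0.073 in 129P2 (mean log2 units ± SD, n = 5), and B6 lay above the other 3 strains together by 0.109 (exact two-sided permutation p = 0.0174, 15504 relabellings). That p is not adjusted for singling out B6, and the array of widest spread was NZO replicate 1 (2.495). Within strains this spread followed the first principal component, which held 23.5% of the variance (Pearson's r = -0.96 and Spearman's rho = -0.93 over 20 arrays, both as deviations from strain means, permutation p = 1e-05 for each, the smallest that 100000 permutations can give; adjusted 2e-05 and 3e-05 over the 3 components examined). Without the 2 arrays farthest from the median spread, r was -0.94. The second component, with 16.3% of the variance, followed spread too (r = 0.93, rho = 0.88, permutation p = 1e-05 and 6e-05, adjusted 2e-05 and 9e-05), with r = 0.89 without those 2 arrays. With array spread as a covariate in the limma fit, 6948 of 14190 tested genes (49%) followed it at an adjusted p under 0.05.

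**Figure D1:**
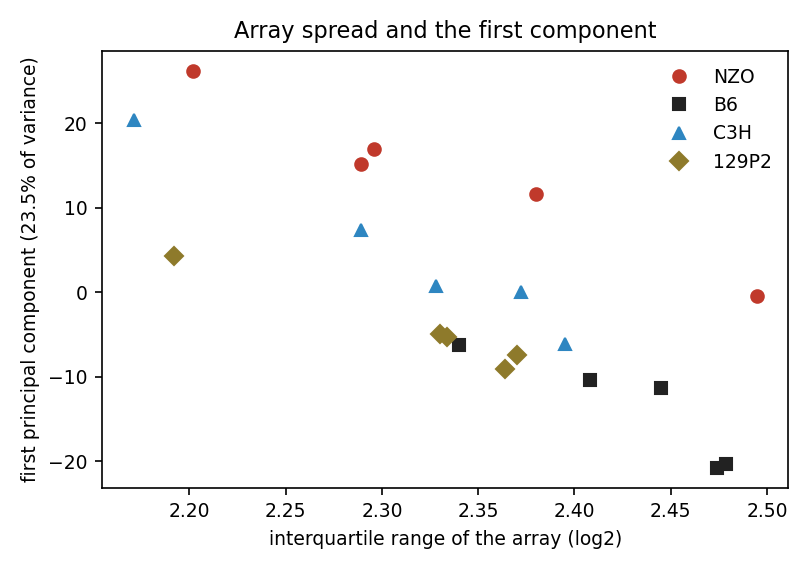
Interquartile range of each array's log2 values (x axis, log2 units) against its position on the first principal component (y axis, arbitrary units), 1 point per animal and 1 symbol per strain. Arrays of narrower spread tend to sit higher within each strain, and the component's within-strain correlation with spread is -0.96.

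The first question was where Nudt19 stood, since the series is named for it. Nudt19 (probe set 10562480) was lower in NZO liver than in each other strain. Its mean was 7.48 ± 0.16 in NZO, 8.75 ± 0.12 in B6, 8.69 ± 0.12 in C3H and 8.39 ± 0.28 in 129P2 (log2, SD, n = 5). The NZO signal was 41.4% of that in B6, 43.3% of that in C3H and 53.1% of that in 129P2. It comes from 1 probe set, and sequence differences between the strains under its probes were not tested. The log2 differences were -1.27 (95% interval -1.50 to -1.05), -1.21 (-1.43 to -0.98) and -0.91 (-1.14 to -0.69), each with an SE of 0.11, and limma's adjusted p was 2.48e-08, 6.25e-08 and 4.62e-06. All 5 NZO values lay below every value of the other strains, so each exact two-sided permutation test gave p = 0.00794, the smallest that 252 relabellings of 5 against 5 animals allow (0.0159 after Benjamini-Hochberg adjustment over 6 comparisons). The arrays were made to find candidate genes, so Nudt19 may have been chosen from them, and its p-values are then not independent evidence. Called genes without overlap of values numbered 995 against B6, 707 against C3H and 868 against 129P2. Among the 173 genes lower in NZO than in all 3 other strains, Nudt19 ranked 29 by its smallest difference. The other strains did not differ past limma's threshold: 129P2 minus B6 was -0.36 ± 0.11 (SE; adjusted p = 0.0516), C3H minus B6 was -0.06 ± 0.11 (adjusted p = 0.733) and C3H minus 129P2 was 0.30 ± 0.11 (adjusted p = 0.144). The exact test of 129P2 against B6 gave p = 0.0159 (adjusted 0.0239).

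**Figure D2:**
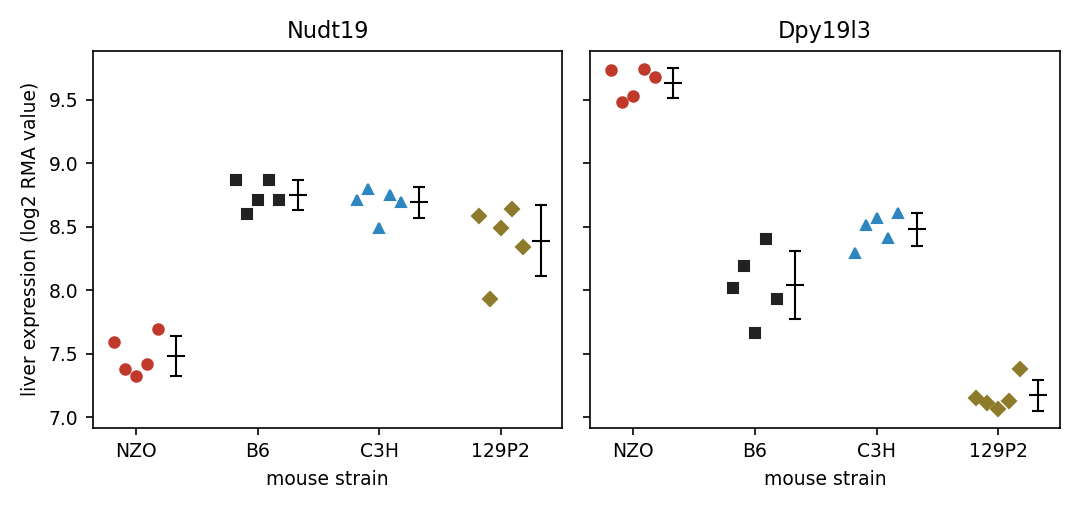
Liver expression of Nudt19 and of its neighbour Dpy19l3 (y axis, log2 RMA value) in 5 animals of each strain (x axis); points are animals, and the bar beside them gives the mean and SD. Nudt19 is lowest in NZO at 7.48 ± 0.16, and Dpy19l3 is highest there at 9.63 ± 0.12.

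Most genes beside Nudt19 did not differ between NZO and the other strains. Of the 12 measured neighbours, 6 on each side in the gene order of the GRCm38.p6 annotation, 10 were past the threshold in no NZO comparison. Dpy19l3, a C-mannosyltransferase 3 measured genes away, went the opposite way and was higher in NZO by 1.59 ± 0.10 against B6, 1.15 ± 0.10 against C3H and 2.46 ± 0.10 against 129P2 (SE; limma's adjusted p = 3.79e-10, 7.46e-08 and 1.36e-13). Rhpn2, also 3 genes away, was lower than in B6 by limma (-0.51 ± 0.15, adjusted p = 0.0304) and than in 129P2 (-0.52 ± 0.15, adjusted p = 0.0280), with -0.29 ± 0.15 against C3H (adjusted p = 0.361). The 12 neighbours were taken for their place, and Rhpn2 is named because its values were seen to pass the threshold.

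Few other genes of coenzyme A metabolism differed. Of all tested genes 10.3%, 6.6% and 8.9% were called against B6, C3H and 129P2, so a list of this size would hold few calls in any case. Of 15 measured genes of coenzyme A synthesis and degradation, Nudt19 and Coasy, the bifunctional enzyme that completes coenzyme A (-0.40 ± 0.10, limma adjusted p = 0.00964), were lower in NZO than in B6, and only Nudt19 differed from 129P2. Against C3H the pantetheinases Vnn1 (1.61 ± 0.25) and Vnn3 (1.38 ± 0.14) were higher in NZO (adjusted p = 0.000113 and 4.13e-07), Vnn1 being dim on 3 of the 5 C3H arrays. Both were among the genes that set C3H apart, lower there than in each other strain. As a list these genes were not called in any NZO comparison (camera adjusted p = 0.575, 0.988 and 0.326 against B6, C3H and 129P2). Of 19 measured Nudix hydrolases, Nudt13 was higher in NZO in all 3 comparisons (0.30, 0.31 and 0.28, SE 0.06 each), and Nudt4 was lower than in B6 (-0.48 ± 0.09) and 129P2 (-0.42 ± 0.09). Against 129P2, Nudt14 was lower too (-0.32 ± 0.09, SE; limma adjusted p = 0.0260), a call lost without NZO replicate 2 or 3 (0.0743 and 0.0667) and without 129P2 replicate 3, 4 or 5 (0.0843, 0.0806 and 0.0590). Dcp2, an mRNA decapping enzyme, was higher there (0.29 ± 0.08, adjusted p = 0.0341). That call was lost with only both strains in the fit (0.0783), with no filter on dim genes (0.0513), with another quantile normalization (0.0591), without the 3 arrays of narrowest spread (0.0578), and without NZO replicate 1, 3 or 5 (0.0941, 0.0742 and 0.0523) or 129P2 replicate 2 or 5 (0.103 and 0.0691). That list was not called either (camera adjusted p = 0.248, 0.238 and 0.724).

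Over the 4 strains, 2415 of 14190 tested genes (17%) differed by limma's moderated F-test at an adjusted p under 0.05. NZO differed from B6 in 1457 genes, from C3H in 936 and from 129P2 in 1263. C3H differed from B6 in 1142 genes, 129P2 from B6 in 879 and C3H from 129P2 in 714. Called genes with at least a 2-fold difference numbered 127, 129 and 132 in the 3 NZO comparisons and 79, 77 and 101 in the others. In the 3 comparisons with B6 most calls were higher in B6: 942 against 515 with NZO, 758 against 384 with C3H and 579 against 300 with 129P2. With array spread as a covariate, a setting chosen after the data were seen, that excess was gone (667 higher in B6 and 711 lower against NZO, 407 and 437 against C3H, 423 and 517 against 129P2), and 999 of the 1457 NZO minus B6 calls, 588 of the 1142 C3H minus B6 calls and 603 of the 879 129P2 minus B6 calls were still made with the same sign.

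**Figure D3:**
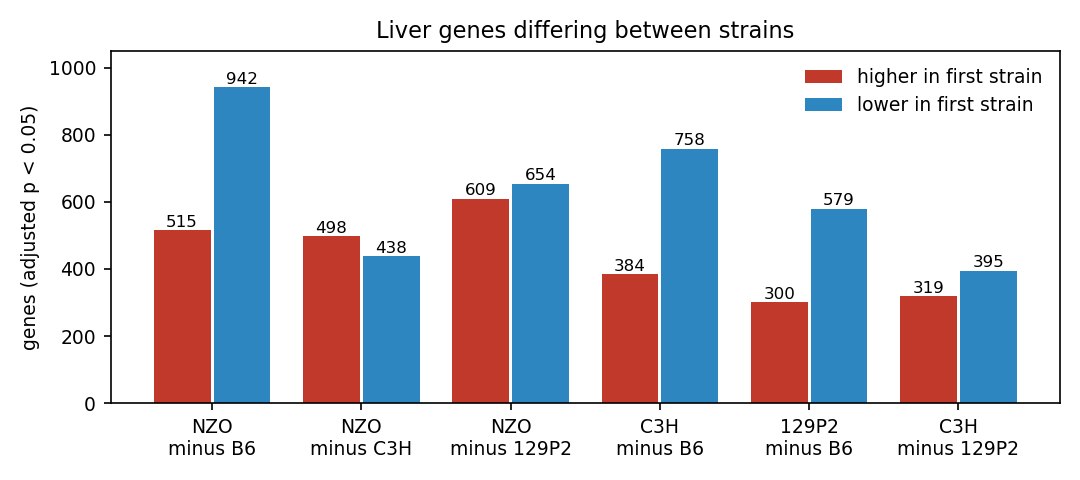
Number of genes at an adjusted p under 0.05 (y axis) in each pairwise comparison (x axis), as bars for genes higher and lower in the strain named first. The lower bars are clearly the longer ones in the 3 comparisons with B6 (942, 758 and 579 genes), where B6 is the strain with the widest arrays on average.

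The next question was which genes set NZO apart from every other strain. There were 311 such genes, 138 higher and 173 lower in NZO than in B6, C3H and 129P2. Independent lists of the same lengths would share 0.78 and 1.34, but these comparisons share the NZO animals, so their lists are not independent. Akr1c18, the aldo-keto reductase that inactivates progesterone, stood out with a mean of 11.30 ± 0.32 in NZO against 6.30 ± 0.59 in B6, 6.01 ± 0.14 in C3H and 5.93 ± 0.04 in 129P2 (log2, SD, n = 5). It was dim on 4 of 5 B6 arrays and on all 5 of C3H and of 129P2. NZO was at least 25.3-fold above C3H and at least 25.4-fold above 129P2. The serum amyloid A genes Saa1, Saa2 and Saa3, acute phase proteins, were higher by 1.96 to 4.12 log2 units over the 3 comparisons. Higher too were Fgl1, a fibrinogen-like protein secreted by hepatocytes (1.56, 1.79 and 1.85, SE 0.15), Acnat2, an acyl-CoA N-acyltransferase (2.02, 1.61 and 1.76, SE 0.27), Zfp949 (1.67, 1.68 and 1.51, SE 0.11), Bin2 (1.62, 1.69 and 1.18, SE 0.17), and Gucy2c, the guanylin receptor (1.47, 1.16 and 1.15, SE 0.18); each trio gives the differences from B6, C3H and 129P2. Mx1, an interferon-induced GTPase, was dim on all 5 arrays of each other strain and higher in NZO by at least 0.87, 0.81 and 0.81. Gucy2c was dim on 2 B6 arrays and Acnat2 on 1.

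Among genes lower in NZO, Akr1c12, another aldo-keto reductase, differed by -2.69, -2.37 and -2.33 (SE 0.15) from B6, C3H and 129P2. The glutathione transferase Gstm6 differed by -3.06, -2.32 and -2.24 (SE 0.13), and Gstm3 by -1.91, -1.50 and -2.25 (SE 0.17). Averaged over its probe sets, Gstm3 was lower still in each comparison. The cytochromes Cyp2c37, Cyp2c50 and Cyp2c29 were lower by 1.80 to 2.70 log2 units in size, and Cyp39a1, an oxysterol hydroxylase of bile acid synthesis, differed by -2.29, -2.21 and -2.00 (SE 0.26). Igfbp2, which binds insulin-like growth factors, had a mean of 9.42 ± 0.47 in NZO against 11.42 ± 0.25, 11.32 ± 0.36 and 11.70 ± 0.16 (log2, SD, n = 5) in B6, C3H and 129P2. Wfdc21 was lower too (-1.83, -2.31 and -2.39, SE 0.17), and Mx2, the neighbour of Mx1, was dim on all 5 NZO arrays and lower there by at least 0.31, 0.45 and 0.34. On NZO arrays Gstm6 was dim on 2, Akr1c12 on 3 and Cyp39a1 on 4. With each dim value raised to its array's percentile, the differences of Akr1c12 were -2.44, -2.12 and -2.08 and those of Cyp39a1 -1.85, -1.77 and -1.56. For these 20 genes the NZO animals lay outside the range of every other strain, as the rule that chose them requires. Limma's adjusted p, under 0.05 by the same rule, was at most 0.00096 in each comparison. Akr1c, Saa, Gstm, Cyp2c and Mx genes have close copies that a probe set can also bind, so which member differed is uncertain, more so as Mx1 with Mx2 and Akr1c18 with Akr1c12 went opposite ways.

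**Figure D4:**
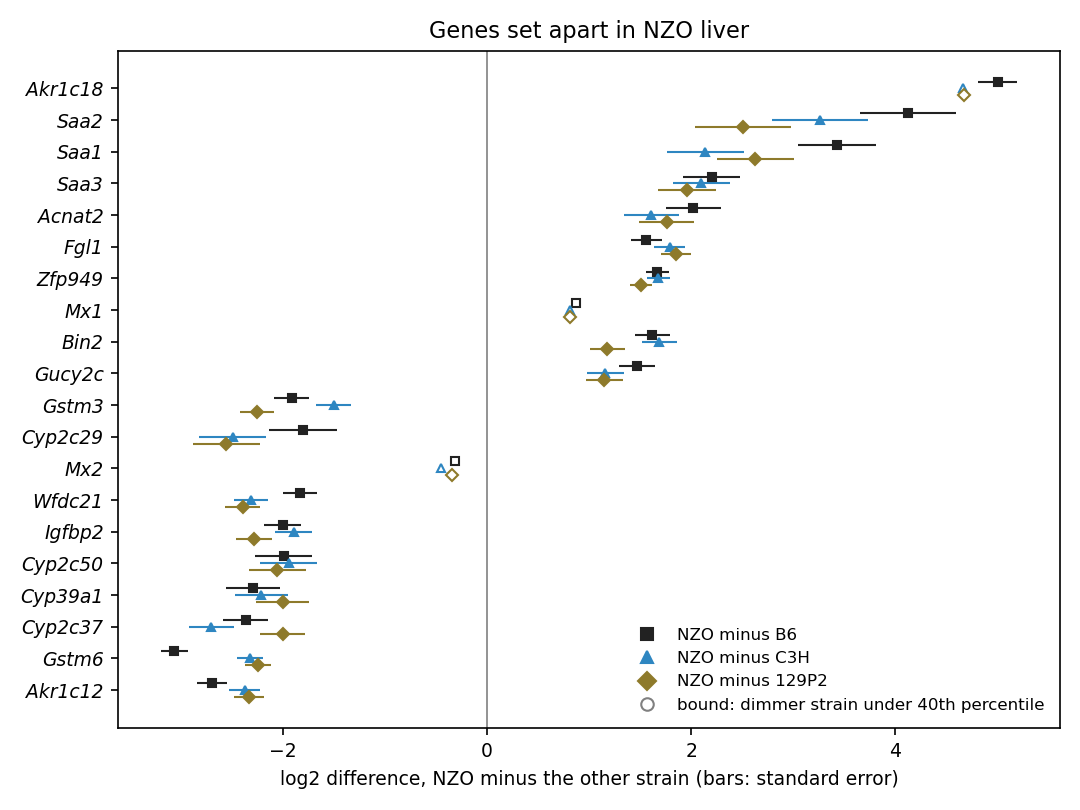
Log2 difference between NZO and each other strain (x axis, log2 units, bars are standard errors) for the 10 genes higher and 10 genes lower in NZO with the largest smallest fitted difference, among set-apart genes whose NZO values overlap with those of no other strain (y axis); open symbols are bounds, for genes dim on all 5 arrays of the dimmer strain. Akr1c18 lies at 4.66 or more against C3H and 4.67 or more against 129P2, and the lower genes with filled symbols lie between -3.06 and -1.50.

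In NZO minus B6, among called genes whose values did not overlap between the strains, Akr1c18, Saa2, Saa1 and Mt2 had the largest fitted differences on the higher side and Gstm6 and Adh6-ps1 on the lower side. Moxd1, a monooxygenase of unknown substrate whose values did overlap, was higher by 3.52 ± 0.64 (SE; limma adjusted p = 0.00069) and dim on 2 of 5 B6 arrays. Besides the genes already named, Mt2, a zinc-binding metallothionein, was higher by 3.35 ± 0.66 (SE; limma adjusted p = 0.00162), Cyp2c39 by 2.93 ± 0.33 (adjusted p = 1.6e-06) and Apcs, the serum amyloid P component, by 2.41 ± 0.13 (adjusted p = 1.66e-11). Lower in NZO were Adh6-ps1, an alcohol dehydrogenase pseudogene (-2.99 ± 0.21), the epoxygenase Cyp2c23 (-2.93 ± 0.16), Ddah1, which degrades asymmetric dimethylarginine (-2.81 ± 0.20), and Trim12a, dim on all 5 NZO arrays and lower by at least 1.19, with adjusted p of 1.14e-09 or less. Apcs and Cyp2c39, with Adh6-ps1 and Trim12a on the other side, were also among the genes that set B6 apart from all 3 strains.

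In NZO minus C3H, Tff3, a trefoil peptide (-3.21 ± 0.24), and the ion channel Asic5 (-2.53 ± 0.10) were lower in NZO by limma (SE; adjusted p = 3.26e-09 and 1.11e-13). Obp2a, an odorant-binding protein, and the peptidase Mme were dim on all 5 NZO arrays and lower there by at least 2.10 and 1.88 (adjusted p = 1.98e-05 and 3.63e-11). The steroid dehydrogenase Hsd3b2 was higher by 2.09 ± 0.16 (adjusted p = 4.24e-09), and Nat8f5, an N-acetyltransferase-like protein dim on all 5 C3H arrays, by at least 1.71 (adjusted p = 5.33e-06).

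In NZO minus 129P2, Moxd1 was higher by at least 4.31 (limma adjusted p = 2.32e-05), with an NZO mean of 10.94 ± 1.04 and a 129P2 mean of 6.21 ± 0.16 (log2, SD, n = 5), dim on all 5 arrays. Serpina12, the adipokine vaspin, was higher by 2.58 ± 0.35 (SE; adjusted p = 2.05e-05). Lower in NZO were the protease Ctse (-2.89 ± 0.19), Cyp2c38 (-2.88 ± 0.47), Cyp2c23 (-2.85 ± 0.16), Asic5 (-2.62 ± 0.10) and Ddah1 (-2.47 ± 0.20), with adjusted p of 0.000225 or less; Cyp2c38 was dim on 3 of 5 NZO arrays, and its difference was -2.43 with dim values raised to their arrays' percentiles.

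These comparisons share the NZO animals, which adds to the overlaps between them. NZO minus B6 and NZO minus C3H shared 189 higher and 256 lower genes, where independent lists would share 18.1 and 29.1. The comparisons with B6 and 129P2 shared 213 and 347 (22.1 and 43.4 for independent lists), and those with C3H and 129P2 shared 248 and 228 (21.4 and 20.2). Simulated strains without differences shared 0 in 20 simulations, which is chance with no effect and shows nothing of what shared animals add to real differences. With the NZO animals split between the paired comparisons, so that none was used in both, the mean numbers over 10 splits were 94.5 and 103 for B6 with C3H (8.6 and 10.2 for independent lists), 105.1 and 128.7 for B6 with 129P2 (10.8 and 14.3), and 119.4 and 97.9 for C3H with 129P2 (8.1 and 6.7).

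Acute phase genes were higher in NZO than in every other strain. Of 28 measured, 17 rose and 1 fell against B6, 14 rose and 1 fell against C3H, and 12 rose and 1 fell against 129P2 by limma over all genes; adjusted over the list alone, 23, 19 and 17 rose and 2, 1 and 1 fell. Saa2 led against B6 and C3H (4.12 ± 0.47 and 3.26 ± 0.47, SE) and Saa1 against 129P2 (2.63 ± 0.38). The camera adjusted p was 1.59e-14, 8.15e-15 and 1.29e-09 against B6, C3H and 129P2 with a preset correlation, and not past the threshold with an estimated correlation (adjusted p = 0.153, 0.102 and 0.150). Neutrophil markers moved in the same direction against B6, with a median difference of 0.17 and 2 of 8 higher, Lcn2 (2.01 ± 0.55) and S100a9 (0.39 ± 0.11). The call of Lcn2 was lost with array spread as a covariate (limma adjusted p = 0.123), with robust moderation (0.0591), without B6 replicate 4 (0.0605) and without NZO replicate 2 or 3 (0.0798 and 0.0667). That of S100a9 was lost with another quantile normalization (0.0674), without the 3 arrays of narrowest spread (0.0804), without B6 replicate 2 or 4 (0.0603 and 0.0798) and without NZO replicate 1 or 2 (0.0608 and 0.0808). Adjusted over the list alone 4 were higher. Lcn2 is on both lists. Camera gave adjusted p = 0.00491, 0.206 with an estimated correlation and 0.0595 with array spread as a covariate. Against C3H and 129P2 that list was not called (camera adjusted p = 0.0554 and 0.114), and against C3H it was with the covariate (0.0342, and 0.190 with an estimated correlation). Genes of the endoplasmic reticulum stress response were higher too, with 7, 5 and 15 of 26 higher and 0, 0 and 1 lower; Hyou1 (0.97 ± 0.18) and Hspa5 (0.70 ± 0.15), chaperones of that compartment, were higher than in 129P2 and Pdia6 (0.52 ± 0.08) than in B6. Camera gave adjusted p = 0.00491, 0.00524 and 1.61e-09, and 0.569, 0.577 and 0.104 with an estimated correlation. By fry the call against C3H was lost (adjusted p = 0.119). Hspa5 and Hyou1 stood out for low values in 129P2. Hspa5 was 12.49 ± 0.17 in NZO, 12.36 ± 0.22 in B6, 12.48 ± 0.13 in C3H and 11.79 ± 0.45 in 129P2 (log2, SD, n = 5). Hyou1 was 10.52 ± 0.27, 10.43 ± 0.24, 10.27 ± 0.22 and 9.55 ± 0.48 in that order. With array spread as a covariate C3H was above 129P2 too, with 8 of 26 higher and 0 lower (camera adjusted p = 0.000134, and 0.505 with an estimated correlation).

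Xenobiotic and bile acid genes were lower in NZO. Of 16 measured targets of the nuclear receptors CAR and PXR, 9 fell and 1 rose against B6, 9 fell and 2 rose against C3H, and 11 fell and 2 rose against 129P2. Adjusted over the list alone, 10, 11 and 11 fell and 2 rose each time. The list's median difference was -0.77, -1.07 and -1.21, and its leading genes were Cyp2c37, Cyp2c29, Gstm3 and Cyp3a11, the main drug-metabolizing cytochrome (-2.05 ± 0.39 against B6 and -2.15 ± 0.39 against 129P2, SE). Camera gave adjusted p = 5.6e-07, 2.45e-08 and 1.34e-10; with an estimated correlation only the comparison with 129P2 was past the threshold (adjusted p = 0.153, 0.102 and 0.0342), and with array spread as a covariate as well it was not (0.0530). Of 17 NRF2 targets, the antioxidant response genes, 5, 4 and 5 fell and 0, 1 and 0 rose, led by Gstm3 and Gstm1 (-1.64, -1.30 and -1.85, SE 0.14); camera gave adjusted p = 0.000634, 0.0177 and 8.81e-05, and 0.569, 0.669 and 0.348 with an estimated correlation. The call against C3H was also lost without NZO replicate 2 (adjusted p = 0.091) and without C3H replicate 2 or 5 (0.0619 and 0.051). So it was by fry (0.152) and without the 3 arrays of narrowest spread (0.06). Of 22 bile acid genes, 6, 6 and 4 fell and 1, 0 and 1 rose, with the transporters Abcc3 (-1.39, -1.89 and -1.37, SE 0.19), Slco1a4 (-1.22, -0.96 and -2.06, SE 0.21) and Abcb11, the bile salt export pump (-0.65, -0.63 and -0.87, SE 0.11). That list's camera adjusted p was 0.0204, 0.00121 and 0.00167, and 0.569, 0.396 and 0.374 with an estimated correlation. Against B6 it was not past the threshold with array spread as a covariate (adjusted p = 0.131), nor with a stricter filter on dim genes (0.135), without NZO replicate 2 (0.0715) or without B6 replicate 2 (0.0556). Nor did it pass there by fry (0.0505) or without the 3 arrays of narrowest spread (0.0759).

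De novo lipogenesis was lower in NZO than in B6, with 9 of 23 genes lower and none higher, among them the desaturase Scd1 (-1.91 ± 0.25), the fatty acid synthase Fasn (-1.39 ± 0.30) and the elongase Elovl6 (-1.13 ± 0.24). Against C3H 7 fell, led by malic enzyme Me1 (-1.38 ± 0.23), and against 129P2 2 fell. Adjusted over the list alone, 14, 10 and 2 fell. Camera gave adjusted p = 3.93e-09, 9.19e-08 and 0.0553, and 0.206, 0.214 and 0.630 with an estimated correlation. Against 129P2, 4 fell with array spread as a covariate (camera adjusted p = 0.0437, and 0.529 with an estimated correlation). Cholesterol synthesis was higher in NZO than in 129P2 in 11 of 20 genes, with Cyp51 (1.77 ± 0.28), Sqle (1.65 ± 0.32) and Msmo1 (1.55 ± 0.31), sterol-forming enzymes, in the lead (camera adjusted p = 4.1e-09, and 0.316 with an estimated correlation). Against B6 it was not called (0 higher and 1 lower; camera adjusted p = 0.890). Against C3H 1 of 20 fell, Sc5d (-0.67 ± 0.12), with camera adjusted p = 0.00100, 0.669 with an estimated correlation and 0.303 by fry. Of these genes 3 fell against C3H with array spread as a covariate. The series title names fatty acid oxidation. Its mitochondrial genes were not called as a list against B6 or C3H (camera adjusted p = 0.218 and 0.0804, median differences -0.05 and -0.08). Against 129P2 their camera adjusted p was 0.0272 with 1 of 27 genes lower, Acad12 (-0.72 ± 0.13), and that call was lost with an estimated correlation (adjusted p = 0.671), by fry (0.325), with a stricter filter on dim genes (0.0861), without NZO replicate 2 (0.193) and without 129P2 replicate 3 (0.303). Against C3H and 129P2 it passed the preset camera with array spread as a covariate (adjusted p = 0.0126 and 0.00573), with 4 genes lower in each and 1 and 0 higher, and did not pass with an estimated correlation (adjusted p = 0.559 and 0.464). Peroxisomal fatty acid oxidation, with 23 measured genes, was not called as a list in any NZO comparison (camera adjusted p = 0.105, 0.269 and 0.447), though 6, 2 and 3 genes were lower and 2, 2 and 4 higher than in B6, C3H and 129P2. With the covariate 2, 3 and 5 were lower and 4, 2 and 4 higher. PPAR alpha targets passed the preset camera against B6 and 129P2, with medians of -0.23 and -0.21, but not fry (adjusted p = 0.116 and 0.0887). The tricarboxylic acid cycle passed camera against each strain, with medians of -0.17, -0.09 and -0.13, but not fry (0.13, 0.384 and 0.222). Acyl-CoA thioesterases passed camera against 129P2, but not with the covariate (0.0575). No such call held with an estimated correlation.

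Interferon response genes were higher in NZO than in C3H and 129P2. Of 38 interferon response genes, 18 rose and 2 fell in NZO against C3H and 29 rose and 2 fell against 129P2, with Irf7, a master regulator of that response (1.15 ± 0.20 and 1.52 ± 0.20), and Ifi27 (0.95 ± 0.14 and 1.62 ± 0.14). Against B6, 2 rose and 5 fell (5 and 5 with array spread as a covariate, where the median difference was 0.13 and the list was not called). Camera gave adjusted p = 8.15e-15, 2e-24 and 0.295, and 0.201, 0.067 and 0.818 with an estimated correlation, for C3H, 129P2 and B6. Antigen presentation by MHC class I moved alike, with 4 and 7 of 15 genes higher and 0 and 1 lower than in C3H and 129P2, among them the immunoproteasome subunit Psmb8 (0.76 ± 0.11 and 1.21 ± 0.11); camera gave adjusted p = 3.31e-06 and 3.26e-08, and 0.102 and 0.0342 with an estimated correlation (against 129P2 0.0530 with the covariate as well). MHC class II was lower in NZO than in 129P2, with 5 of 9 genes lower and 1 higher, H2-Aa (-1.89 ± 0.28), H2-Ab1 (-1.84 ± 0.26) and Cd74 (-1.49 ± 0.24) in the lead (camera adjusted p = 0.00115, and 0.250 with an estimated correlation). Against C3H that list passed camera in the opposite direction, with a median difference of 0.39, 0 of 9 genes past limma's threshold and 3 higher adjusted over the list alone (camera adjusted p = 0.00524, 0.396 with an estimated correlation and 0.063 by fry). H2-Aa was 8.43 ± 0.27 in NZO, 9.60 ± 0.49 in B6, 7.78 ± 0.38 in C3H and 10.32 ± 0.75 in 129P2 (log2, SD, n = 5). Sequence differences between the strains under the probes of MHC class II genes were not tested. Complement and coagulation genes were higher in 6 of 34 against C3H and 10 of 34 against 129P2, with C4a at 1.76 ± 0.15 and 0.87 ± 0.15 (camera adjusted p = 0.000122 and 8.35e-05, and 0.577 and 0.449 with an estimated correlation). Against B6, 7 were higher and 2 lower, and the list was not called (camera adjusted p = 0.0707, and 0.707 with an estimated correlation). There it was called with array spread as a covariate (0.000653, and 0.517 with an estimated correlation), with 8 higher and 1 lower.

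Among markers of other liver cells, endothelial markers were lower in NZO in 12 of 19 genes against B6, 10 against C3H and 10 against 129P2, with none higher, and 14, 12 and 14 were lower when adjusted over the list alone. The vascular receptor Kdr differed by -0.66, -0.69 and -0.74 and the angiopoietin receptor Tek by -0.60, -0.48 and -0.52. Camera gave adjusted p = 6.02e-09, 6.1e-10 and 6.5e-10, and 0.235, 0.182 and 0.150 with an estimated correlation. Markers of stellate cells and fibrosis were lower in 8, 4 and 6 of 22 genes, with Ecm1, an extracellular matrix protein, at -0.66, -0.62 and -0.86 (SE 0.11). Camera gave adjusted p = 4.46e-06, 0.00185 and 3.95e-05, and 0.447, 0.582 and 0.348 with an estimated correlation. By fry the stellate call against C3H was lost (adjusted p = 0.132). With the preset correlation both lists stayed past camera's threshold in each comparison under the array spread covariate, and with an estimated one neither passed (smallest adjusted p = 0.0613). Against B6, 6 endothelial and 4 stellate genes were then lower by limma. Against C3H, 7 stellate genes were. Hepatocyte markers were not called (camera adjusted p = 0.700, 0.402 and 0.894), nor were those of cholangiocytes, B cells and plasma cells, T and NK cells or pancreatic acinar cells in any NZO comparison. Kupffer cell and macrophage genes were higher in 3 of 20 against C3H, Mpeg1 (1.35 ± 0.17), Folr2 (1.11 ± 0.17) and Lyz2 (1.10 ± 0.25), with camera adjusted p = 0.00512, and 0.669 with an estimated correlation. With array weights it was 0.0879, and by fry 0.217. That list was not called against B6 or 129P2 (median differences -0.12 and -0.06). Erythroid genes were higher in 3, 1 and 3 of 5 genes, with Bpgm, a red cell enzyme, at 0.37, 0.44 and 0.53 (SE 0.09); camera gave adjusted p = 0.00567, 0.0250 and 8.81e-05, and 0.153, 0.182 and 0.0243 with an estimated correlation (against 129P2 0.0530 with the covariate as well). The erythroid call against C3H was lost without C3H replicate 2 (adjusted p = 0.0625) and with no filter on dim genes (0.137). Adipocyte markers were lower than in C3H by the preset camera, but not with an estimated correlation. That call was also lost with array spread as a covariate (adjusted p = 0.0635), with array weights (0.101) and with a stricter filter on dim genes (0.0535). Leaving out NZO replicate 1 (0.113) or C3H replicate 2 (0.0647) lost it too.

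**Figure D5:**
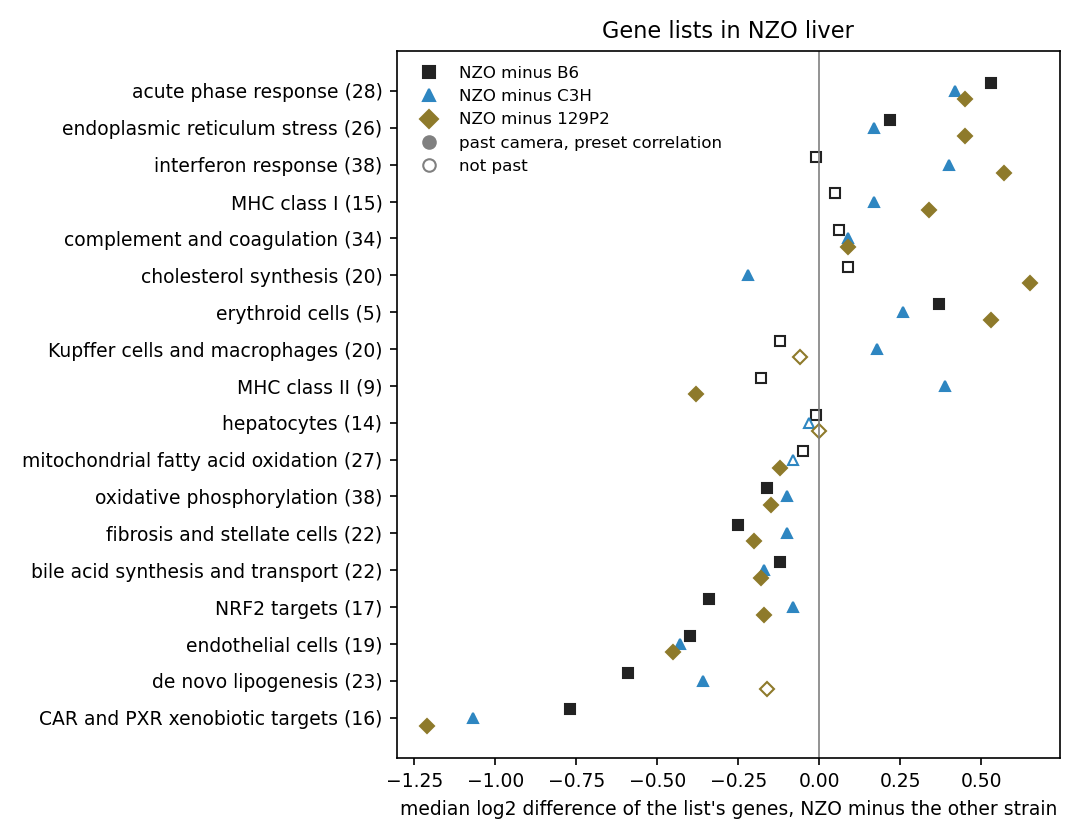
Median log2 difference (x axis, log2 units) of the measured genes of 18 lists (y axis, number of genes in brackets) between NZO and each other strain; filled symbols are past camera's threshold with a preset correlation. The CAR and PXR targets have the lowest medians (-0.77, -1.07 and -1.21), and with an estimated correlation only those targets, MHC class I and erythroid genes keep a call, all against 129P2 and none once array spread is a covariate as well.

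Of 45 lists tested, 18 were past camera's threshold against B6, 21 against C3H and 24 against 129P2 with the preset correlation, and 0, 0 and 3 with an estimated one, where 6, 8 and 9 lists had an unadjusted p under 0.05. By fry, which tests whether a list's genes move on balance in 1 direction without setting them against other genes, 15, 12 and 19 passed. Energy metabolism lists were among those past the preset camera with small shifts. Oxidative phosphorylation had median differences of -0.16, -0.10 and -0.15 with 2, 0 and 1 of 38 genes lower (camera adjusted p = 0.000111, 0.00524 and 0.000111, and 0.569, 0.738 and 0.559 with an estimated correlation). The covariate of array spread gave 1, 2 and 9 lower. Against B6 that list was lost with the covariate (adjusted p = 0.175), and against C3H without NZO replicate 2 or 3 (0.212 and 0.205) or C3H replicate 2 (0.0619). By fry that list passed in no NZO comparison (adjusted p = 0.106, 0.391 and 0.171 against B6, C3H and 129P2).

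Between the strains other than NZO, C3H and 129P2 were lower than B6 in interferon response genes, with 22 and 30 of 38 genes lower and none higher; Irf7 differed by -0.97 ± 0.20 and -1.34 ± 0.20 (SE), and camera gave adjusted p = 2.8e-15 and 3.54e-34, and 0.851 and 0.0783 with an estimated correlation. Under the array spread covariate 9 and 23 of the 38 were lower. The median difference was then -0.27 in place of -0.42 for C3H and -0.48 in place of -0.61 for 129P2. Cholesterol synthesis was lowest in 129P2, with 9 of 20 genes lower than in B6 and 16 of 20 higher in C3H than in 129P2; Cyp51 differed by -1.45 ± 0.28 and 1.82 ± 0.28 (camera adjusted p = 2.81e-10 and 1.01e-21, and 0.660 and 0.257 with an estimated correlation). Under the covariate 2 of 20 were lower in 129P2 than in B6, with a median difference of -0.57 in place of -0.60. MHC class II genes were lower in C3H than in 129P2 in 6 of 9 genes and higher in 1, H2-Aa differing by -2.54 ± 0.28 (camera adjusted p = 9.9e-07, and 0.257 with an estimated correlation). Sequence differences under their probes were not tested here either. Among called genes whose values did not overlap, the largest fitted differences each way were Asic5 (2.75 ± 0.10) and Adh6-ps1 (-3.25 ± 0.21) in C3H minus B6, Cyp2c39 (4.61 ± 0.33) and Adh6-ps1 (-3.37 ± 0.21) in 129P2 minus B6, and Tff3 (3.34 ± 0.24) and Ctse (-3.94 ± 0.19) in C3H minus 129P2. Adh6-ps1 was dim on 1 C3H and 2 129P2 arrays. Ctse was also higher in 129P2 than in B6 (3.87 ± 0.19). Cyp2c38 was lower in C3H than in 129P2 (-3.65 ± 0.47; dim on 4 of 5 C3H arrays, and -2.56 with dim values raised to their arrays' percentiles), as was Cyp4a14, dim on all 5, by at least 3.26.

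Each of these strains also had genes that set it apart from the other 3: 204 in B6 (138 higher and 66 lower), 135 in C3H (44 and 91) and 162 in 129P2 (73 and 89). Independent lists would share at most 2.05 in either direction, but the comparisons of a strain share its animals and are not independent. Without B6 replicate 4 the count for B6 was 134, and that for C3H minus B6 was 729. In B6, Bst2, the antiviral protein tetherin, was higher with a mean of 11.16 ± 0.20 against 9.07 ± 0.08 in NZO, 8.98 ± 0.13 in C3H and 8.80 ± 0.08 in 129P2 (log2, SD, n = 5), as were Adh6-ps1, Trim12a and Clec2h, while Apcs, Cyp2c39, Slc17a8 and the lipid transporter Abca3 were lower. In C3H, Cyp46a1, a cholesterol hydroxylase, was higher with 9.57 ± 0.65 against 7.18 ± 0.09, 7.02 ± 0.11 and 7.18 ± 0.07 in NZO, B6 and 129P2, as were Gbp11, Klk1b22 and Tnfsf10, the death ligand TRAIL. Lower in C3H were complement C4b (10.33 ± 0.06 against 12.12 ± 0.21, 12.07 ± 0.10 and 12.15 ± 0.14), Vnn1, the lipid droplet enzyme Hsd17b13 and Plscr2. In 129P2, Ctse (10.76 ± 0.67 against 7.87 ± 0.13, 6.88 ± 0.09 and 6.81 ± 0.08 in NZO, B6 and C3H), Trhde, Cyp2c39 and Slc6a16 were higher, and the carboxylesterase Ces1g, the antitrypsin gene Serpina1d, Ttc23 and Adgrf1 were lower. Of these genes, Trim12a was dim on all 5 arrays of each strain but B6, Klk1b22 on all 5 of each strain but C3H, and Slc6a16 on all 5 of NZO and of B6 and 3 of C3H. Trhde was dim on 3 NZO, 4 B6 and 2 C3H arrays, and Plscr2 on 4 and Vnn1 on 3 of C3H. Cyp2c39, Serpina1d, C4b, Klk1b22 and Trim12a have close copies, so which member differed is uncertain.

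A last list held genes already reported to vary among these or related strains, and since it holds Nudt19 and other genes because of such reports, its direction is not independent evidence. Of its 14 measured genes, 4 were lower in NZO in each comparison and 1, 0 and 1 higher against B6, C3H and 129P2; adjusted over the list alone, 7, 4 and 5 differed. Its camera adjusted p was 0.00902, 0.00265 and 0.000429, and 0.553, 0.396 and 0.246 with an estimated correlation; against B6 it was 0.132 with array spread as a covariate, and against C3H 0.116 with no filter on dim genes. Nnt, the mitochondrial nicotinamide nucleotide transhydrogenase, was lower in B6 than in NZO (0.68 ± 0.12), C3H (0.75 ± 0.12) and 129P2 (0.88 ± 0.12), each given as that strain minus B6 (SE; limma adjusted p = 0.000461, 0.00019 and 2.51e-05). Glo1, the glyoxalase that clears methylglyoxal, was lower in NZO than in C3H (-0.81 ± 0.10) and 129P2 (-1.01 ± 0.10; adjusted p = 4.38e-06 and 1.51e-07), and -0.07 ± 0.10 from B6 (adjusted p = 0.683). Gm4951 was lower in NZO than in B6 (-1.33 ± 0.12) and C3H (-1.35 ± 0.12; adjusted p = 3.28e-08 and 3.64e-08). Its difference from 129P2 (-0.43 ± 0.12, adjusted p = 0.0210) was lost without NZO replicate 4 or 5 or 129P2 replicate 4 or 5 (adjusted p = 0.075, 0.0663, 0.0678 and 0.0596) and with only both strains in the fit (0.0657). Pctp, a phosphatidylcholine transfer protein, was lower than in B6 in NZO (-0.62 ± 0.19, SE; limma adjusted p = 0.0368), C3H (-0.99 ± 0.19, adjusted p = 0.00147) and 129P2 (-0.75 ± 0.19, adjusted p = 0.0166). The NZO call was lost under many settings, among them array spread as a covariate (0.131), array weights (0.0593) and leaving out NZO replicate 2 (0.119), and the 129P2 call with that covariate (0.0917) or without 129P2 replicate 5 (0.0553). Hc, complement C5, was higher in NZO than in 129P2 (0.32 ± 0.09, adjusted p = 0.0184), but not with only both strains in the fit (0.0713), without NZO replicate 1 (0.0536) or without the 3 arrays of narrowest spread (0.0983). Tbc1d1, a regulator of glucose uptake, was lower in C3H than in B6 (-0.36 ± 0.08, adjusted p = 0.00830; 0.0739 with the covariate) and 129P2 (-0.34 ± 0.08, adjusted p = 0.0150). The latter call was lost without C3H replicate 3 (0.0515) and without the 3 arrays of narrowest spread (0.0659). Of the rest, Abcg1, Apoa2, Dpp4, Gbp2b, Ide and Cidec were not past the threshold in any comparison.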

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

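Chosen after the data were seen were array spread as a covariate, the comparison of endothelial and stellate genes with other cell types, the counting of each gene once in the test of second probe sets and the adjustment of the shares of splits over comparisons; the other tests here were set before their results were seen. The named genes and the array interquartile range, each in each strain, gave 696 groups of 5 values. In 45 of these groups 1 animal lay apart from the other 4, its gap to the nearest exceeding 0.71 of the group's range (Dixon's criterion). Chance gives about 1 in 20 independent groups, or 34.8. The values of an animal are not independent over genes and the genes were chosen, mostly for large differences, so that number is a rough guide. B6 replicate 3 had 12 of the 45 and 129P2 replicate 2 had 9. The numbers in the sentences on single animals are gaps as a share of the range.

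B6 replicate 3 was highest in Cyp4a14, a PPAR alpha target (10.60 against 6.88 in the nearest animal, log2; 0.882), in the thioesterases Acot1 (0.816) and Acot2 (0.736), the lipid droplet gene Cidec (0.848), Cyp3a11 (0.930), Cyp3a44 (0.715), Akr1c18 (0.779), Lyz2 (0.71), Mx2 (0.774) and Srxn1 (0.730), and lowest in Dpp4 (0.824) and Hc (0.739). 129P2 replicate 2 was lowest in array interquartile range (0.772), Clec4g (0.864), Cyp4a12a (0.712), Gbp7 (0.835), Gm12250 (0.773), Gstm6 (0.787), Hsd17b13 (0.835) and Ide (0.788), and highest in Wfdc21 (0.726). In other 129P2 animals, replicate 1 was highest in Ppargc1a (0.754) and Tbc1d1 (0.873), replicate 4 in Elovl3 (0.854) and replicate 5 in Dpy19l3 (0.713). B6 replicate 5 was highest in Sdf2l1 (0.898).

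Among C3H animals, replicate 1 was lowest in Pdia4 (0.866), replicate 2 was highest in Gucy2c (0.810) and Mbl2 (0.719) and lowest in Selenbp2 (0.8), replicate 3 was lowest in Gys2 (0.908), Kdr (0.739) and Tek (0.879) and highest in Saa3 (0.758), and replicate 5 was lowest in Trim12a (0.913). Among NZO animals, replicate 1 was highest in Dpp4 (0.734), Gbp2b (0.880) and Lum (0.717), replicate 2 was lowest in Acaa1b (0.768), Acad12 (0.824), Lrat (0.711) and Pdia4 (0.792), and replicate 4 was lowest in Lpl (0.817) and Trim12a (0.804) and highest in Trhde (0.761). No explanation was tested for single animals.

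Endothelial and stellate genes were lower in NZO than in each other strain by camera with the preset correlation. With array spread as a covariate 6 of 6 such tests still passed, so spread alone does not account for them, but with an estimated correlation none passed, with that covariate (adjusted p = 0.259, 0.121 and 0.0613 for endothelial and 0.450, 0.470 and 0.329 for stellate genes against B6, C3H and 129P2) or without it. Against B6, where Kupffer genes too had a median under 0 (-0.12), the covariate took the lists' medians from -0.40 and -0.25 to -0.30 and -0.23, and fewer single genes were called (6 in place of 12 endothelial and 4 in place of 8 stellate). A smaller share of all non-hepatocyte cells would lower every such type alike, but the 41 endothelial and stellate genes had medians of -0.36, -0.25 and -0.32 against B6, C3H and 129P2, at least 0.27 below (difference -0.27 against C3H) the 0.01, 0.02 and 0.02 of 46 genes of Kupffer cells, lymphocytes and cholangiocytes (permutation p over genes = 1e-04 each, the smallest that 10000 permutations can give; genes are not independent replicates), and below Kupffer genes alone by 0.24, 0.44 and 0.26 (adjusted over 24 such tests, permutation p = 0.0081, 0.0008 and 0.0223). Type by type only 5 of 12 such tests without the covariate had an adjusted permutation p under 0.05: T and NK cells (0.0008, 0.151 and 0.055 against B6, C3H and 129P2) and B cells (0.00096, 0.201 and 0.104) were apart only against B6 and cholangiocytes, with a median of -0.18 against B6, in none (0.211, 0.201 and 0.055), so a smaller share of several types, though not of all alike, may be part of this, and fewer cells and less expression in each were not told apart.

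More calls were higher than lower in B6: 65.5% over its 3 comparisons. With array spread as a covariate the share was 47.3%, so the wider spread of the B6 arrays is a candidate explanation of the excess; strain and spread go partly together, and a strain effect on both stays open. Sequence differences from the B6 reference under the probes cannot be told apart from this: a second probe set had the sign of the call in 77 of 89 genes higher in B6 (86.5%) and 23 of 23 lower in B6 (Fisher's exact two-sided p = 0.122), and few genes had such a probe set. Counted over calls, so that a gene could enter up to 3 times, it was 104 of 124 and 29 of 29 (Fisher's exact two-sided p = 0.0146), which would have met the prediction first written; each gene was counted once after that was seen, because calls of a gene repeat.

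Genes that set a strain apart lay next to each other more often than permuted genes, with 50 adjacent pairs against 12.83. Families of similar neighbouring genes, which probes may confuse, were told only by a shared start of the gene symbol. Without pairs of such a family 36 pairs remained against 12.06, a ratio of 3 (permutation p = 1e-04, the smallest that 10000 permutations can give). So families told in this way were not the whole source. The same pair could count in more than 1 strain and the strains were permuted separately, so the pooled p may be too small. By strain the remaining pairs were 17 against 6.39 in NZO (permutation p = 3e-04) and 12 against 2.77 in B6 (2e-04). In C3H they were 5 against 1.17 (0.008) and in 129P2 2 against 1.72 (0.5). Both genes of a pair moved the same way in 13 of 17, 9 of 12, 5 of 5 and 1 of 2. Shared local variants between these strains were not tested.

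For every count of genes, fewer than 5 of 100 groupings of the animals gave as many, the limit set beforehand for chance. Groupings that mix strains put strain differences into the spread within groups, which lowers their counts. A processing difference that goes with strain would pass this test as well, and the labels give no batch. Of 100 splits of the 10 animals compared, the real one included, 1 gave as many genes in each comparison. Fitted with the compared strains alone, the real split and the highest other gave 1368 and 1 genes for NZO minus B6, 853 and 8 for NZO minus C3H, 1091 and 0 for NZO minus 129P2, 988 and 1 for C3H minus B6, 790 and 2 for 129P2 minus B6, and 574 and 1 for C3H minus 129P2. Of 100 regroupings of the 20 animals, 1 reached the 2415 genes of the F-test (highest other 1), and 1 each the 311, 204, 135 and 162 genes set apart in NZO, B6, C3H and 129P2 (highest other 0). For gene lists chance cannot be excluded for NZO minus B6, where 6 of 100 splits gave at least the real 19 lists (highest other 22). For NZO minus C3H (4 of 100; 22 real, highest other 24) and NZO minus 129P2 (2 of 100; 26 real, highest other 26) the share was under the 5 in 100 set beforehand, but after Benjamini-Hochberg adjustment over the 3 comparisons it was 0.06 in each, so chance is left open for them too.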

How the results depend on the processing

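Array spread as a covariate and leaving out the 3 arrays of narrowest spread were chosen after the data were seen. Nudt19 stayed lower in NZO and past limma's threshold in all 3 comparisons under every setting but a fold of at least 2, where its difference from 129P2 (-0.912) fell short by the setting's own construction. Leaving out animals, it ranged from -1.32 to -1.23 against B6, -1.26 to -1.17 against C3H and -1.03 to -0.85 against 129P2. No called difference of a named gene and no list call changed sign under the settings run. The balance of calls did turn with array spread as a covariate, from 515 higher and 942 lower to 711 and 667 for NZO minus B6, from 384 and 758 to 437 and 407 for C3H minus B6, from 300 and 579 to 517 and 423 for 129P2 minus B6, and from 498 and 438 to 656 and 703 for NZO minus C3H. With array weights the F-test gave 4175 genes, NZO minus B6 3165, NZO minus C3H 1430, NZO minus 129P2 2102, C3H minus B6 1889 and C3H minus 129P2 1126, and 556, 353, 204 and 249 were set apart in NZO, B6, C3H and 129P2; the cause was not tested. A test against a fold of 1.2, stricter by construction, gave 251, 220 and 267 for NZO minus B6, C3H and 129P2, 177 for C3H minus B6, 172 for 129P2 minus B6, 162 for C3H minus 129P2, and 70, 34, 36 and 27 set apart in NZO, B6, C3H and 129P2. A fold of at least 2, also stricter, gave 296 in the F-test, then 127, 129, 132, 79, 77 and 101 in the same comparisons and 47, 14, 19 and 19 set apart. With array spread as a covariate NZO minus 129P2 gave 1928 and C3H minus 129P2 1125 genes, and 10 lists passed for NZO minus B6; the cause was not tested. Camera with an estimated correlation passed 0, 0 and 3 lists for NZO minus B6, C3H and 129P2 (unadjusted p under 0.05 in 6, 8 and 9; fry 15, 12 and 19), since it allows for genes that move together; with array spread as a covariate as well it passed 0, 0 and 0. Leaving out each animal gave 1971 to 2817 genes in the F-test, 972 to 2175 for NZO minus B6 (without B6 replicate 4 and NZO replicate 1), 735 to 1029 for NZO minus C3H, 1011 to 1366 for NZO minus 129P2, 729 (without B6 replicate 4) to 1472 (without C3H replicate 2) for C3H minus B6, 646 to 981 for 129P2 minus B6 and 538 to 788 for C3H minus 129P2; set apart were 243 to 355 in NZO, 134 (without B6 replicate 4) to 250 (without NZO replicate 1) in B6, 96 to 146 in C3H and 126 to 169 in 129P2, and 17 to 21, 17 to 23 and 20 to 26 lists passed. Of 63 list calls, fry lost 20 and array spread as a covariate 12, and a stricter filter on dim genes lost 11 of the 57 that had a result under it. The other settings kept every count within 1.5 times. No paired analysis was made, since the strains are separate animals and the labels give no pairing between them. What signal over background limits was not tested beyond the filters on dim genes.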

Other observations

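Some lists not described so far also passed camera in NZO. Female-biased liver genes, 11 measured, were lower in NZO than in 129P2 in 6 (camera adjusted p = 3.15e-07, and 0.067 with an estimated correlation). Against B6 and C3H 4 and 2 were lower and 1 each higher, and the list was not called (0.0612 and 0.5). Male-biased genes, 19 measured, were higher than in 129P2 in 5 and lower in 1, with Nat8f5, dim on all 5 129P2 arrays, higher by at least 1.71 (camera adjusted p = 0.000956, and 0.461 with an estimated correlation). Against B6 that list was called as well (6 higher and 1 lower; camera adjusted p = 0.00902, and 0.569 with an estimated correlation), a call lost with array weights (0.176), without B6 replicate 3 (0.229) and without NZO replicate 1 (0.0596), and against C3H it was not (0.734). By fry the calls against B6 and 129P2 were both lost (adjusted p = 0.126 and 0.0515). All animals were male. Immunity-related GTPases and guanylate-binding proteins, 11 measured, were higher than in 129P2 in 7 and lower in 1 (camera adjusted p = 1.99e-06, and 0.180 with an estimated correlation), and not called against B6 or C3H (0.890 and 0.191). Gluconeogenesis and glycogen genes were lower than in B6 in 6 of 19 (camera adjusted p = 0.00847, 0.447 with an estimated correlation and 0.0595 with array spread as a covariate, where 3 were lower). Against C3H 1 was lower and the list was not called (0.250). Against 129P2 3 were lower and 1 higher (camera adjusted p = 0.0105, and 0.316 with an estimated correlation), a call lost without 129P2 replicate 1 (0.0589). With the covariate 7 were lower and 1 higher there.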
